A study of Homo sapiens with 24 samples.

How the data were processed

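RNA from 24 samples of dopaminergic neurons, differentiated from the human induced pluripotent stem cell line Sigma028, was sequenced as total RNA with a directional library kit. The cells had been exposed to PCB-180, a polychlorinated biphenyl congener, at 0, 10, 500 or 10000 nM, and the labels add a time of t24 or t74 without a unit. The design text describes an exposure of 24 h and later sampling, without saying from when the times were counted, so t74 may lie after the exposure had ended. The 8 groups held 3 samples each. Replicates were numbered by the order in which the samples were deposited, and replicates of the same number also fall in the same run of sample-sheet numbers, the set, in every group. The labels do not say what a set shares. The labels do not say whether the 3 samples of a group were separate cultures. All p-values therefore measure only the spread between these samples, part of which may be technical.

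The authors deposited 1 table per sample with 60676 Ensembl gene identifiers. Per the file headers, the deposited tables hold expected counts, which are estimated read counts that need not be whole. The deposited tables also hold TPM and FPKM, which are scaled for depth and gene length. STAR and RSEM were named per the submitters' processing notes, without versions. The genome build and annotation were not given in the sources used here. Gene symbols came from a table that held 60357 of the identifiers. Coordinates, gene types and GC content came from GENCODE release 29 on GRCh38, which held 58503 of them and may differ from the authors' annotation. Gene lengths were the effective lengths in the deposited tables, averaged over the samples. TPM and FPKM entered no test.

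Expected counts were rounded to whole numbers. Library totals ran from 36566544 to 77038068 counts, with a median of 54875560. Genes were filtered with filterByExpr, which left 25592, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, in R 4.3.3), with 1 fit of 8 groups over all 24 samples. Calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 with their standard error (SE), and levels are CPM, counts scaled by the TMM-adjusted library total, with their standard deviation (SD). The 13 comparisons were each dose against 0 nM at t24 and at t74, each dose averaged over both times, the difference of each dose effect between the times, and t74 against t24 averaged over the doses. The common dispersion corresponded to a coefficient of variation of 45.1% between replicates, and Pearson correlations of log-CPM between replicates of a group lay between 0.923 and 0.973.

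Recovery was tested on simulated data with 50 genes changed by each fold. The changed genes were drawn only from the more abundant genes, and counts were simulated without outlying libraries. Recovery in the real data may therefore be lower. In a comparison of 3 against 3 samples, 20% of genes changed 1.5-fold were called, 66% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, with 4 false calls among 145. In the comparison of 12 against 12 samples, 84% of genes changed 1.5-fold were called and 100% at 2-fold, with 9 false calls among 200.

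A set of 42 gene lists was fixed before the data were examined, for neuron subtypes, other cell types, stress and xenobiotic responses, metabolism and signaling. Each list with 3 or more measured genes was tested with camera (limma 3.58.1) on log-CPM with a preset inter-gene correlation of 0.01, again with a correlation estimated from the residuals, and with fry. Adjusted p-values of lists are Benjamini-Hochberg values over the lists within a comparison. The rule for named genes was also fixed before the data were examined. It took up to 10 rising and 10 falling genes past the threshold with a CPM of at least 1 and sample values that did not overlap between the groups, and up to 4 members of each list with the smallest p. Where fewer than 10 genes passed, it also took the 5 with the smallest unadjusted p. It allowed any dopaminergic, aryl hydrocarbon receptor or Parkinson disease gene on the lists. XIST and Y-linked genes were left out of the tables. Single-gene results for 3 genes of the lists are not reported here.

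Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE size factors, no filter, a filter of CPM 1 in 12 samples, a fit of the compared groups alone, a block for sample-sheet sets and the omission of each library in turn. Limma-voom with sample weights, omission of the 2 libraries with the fewest detected genes, and a correction for gene length and GC content were added after the data had been seen. The samples of each comparison were also regrouped, in all 10 splits of 3 against 3, and in 40 or 100 splits for comparisons over both times. Groups of 3 samples cannot reach an exact permutation p below 0.1, so p-values rest on the spread that edgeR shares between genes. Figures were drawn with matplotlib 3.10.9.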

Results

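The neurons expressed the machinery for making and storing dopamine at every dose and time. Tyrosine hydroxylase (TH, chromosome 11 at 2163929 to 2171877), which catalyses the rate-limiting step of dopamine synthesis, stood at 40.7 ± 10.3 CPM (mean ± SD, n = 24). DDC, the decarboxylase that completes the synthesis, reached 96.9 CPM, and SLC18A2, which loads dopamine into vesicles, 43.4 CPM. The midbrain transcription factors LMX1A, FOXA2 and NR4A2 had means of 99.7, 21.1 and 23.1 CPM. Of the 22 dopaminergic identity genes, 4 had means below 1 CPM: the dopamine transporter gene SLC6A3 (0.35 CPM), EN1 (0.374 CPM), EN2 (0.185 CPM) and PITX3 (0.788 CPM). Others were well above, such as KCNJ6 at 169 CPM and ALDH1A1 at 115 CPM. General neuronal genes were abundant, with MAP2 at 2126 CPM and STMN2 at 1109 CPM.

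Markers of other cell types were present and varied between libraries. TTR, the transthyretin gene that choroid plexus secretes, ranged from 237 to 2372 CPM, and the collagen gene COL1A1 averaged 315 CPM. The proliferation marker MKI67 ranged from 5.92 to 45.3 CPM, PAX6 from 24.2 to 262 CPM and GAD1, the GABA-synthesizing enzyme, from 10.4 to 101 CPM. GFAP, an astrocyte gene, averaged 1.15 CPM. The first principal component held 13.1% of the variance and mainly set apart 500 nM t24 replicate 3, the library with the fewest genes above 0 (20671). The second, with 8.73%, mainly set apart 10000 nM t24 replicate 3 (23079 genes). The other 22 libraries had between 24255 and 29515 genes. In 10 nM t74 replicate 3, mitochondrial transcripts made up 3.61% of counts.

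No single dopaminergic gene changed detectably with PCB-180. At 10000 nM and t74, TH had 49.9 ± 10.7 CPM (SD, n = 3) against 43.0 ± 14.1 CPM without PCB-180, a log2 difference of +0.21 ± 0.24 (SE). At t24 the same dose gave 32.6 ± 4.9 against 34.4 ± 5.97 CPM (−0.07 ± 0.24). Across the 6 comparisons at single times, TH differences lay between −0.07 and +0.26. None of the 22 dopaminergic identity genes passed in any dose comparison, adjusted over all genes or adjusted over the list alone. At t24 the list's median on log-CPM was +0.104, −0.224 and −0.361 at 10, 500 and 10000 nM. Camera did not call the list there (adjusted p = 0.205, 0.349 and 0.0842). The only members at an unadjusted p under 0.05 in a comparison at a single time were both at 10000 nM and t24, where CALB1, a calcium-binding protein of dopaminergic subtypes, was at +0.48 ± 0.17 and LMX1A at −0.57 ± 0.27. The 15 monogenic Parkinson disease genes had 0 calls as well.

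**Figure D1:**
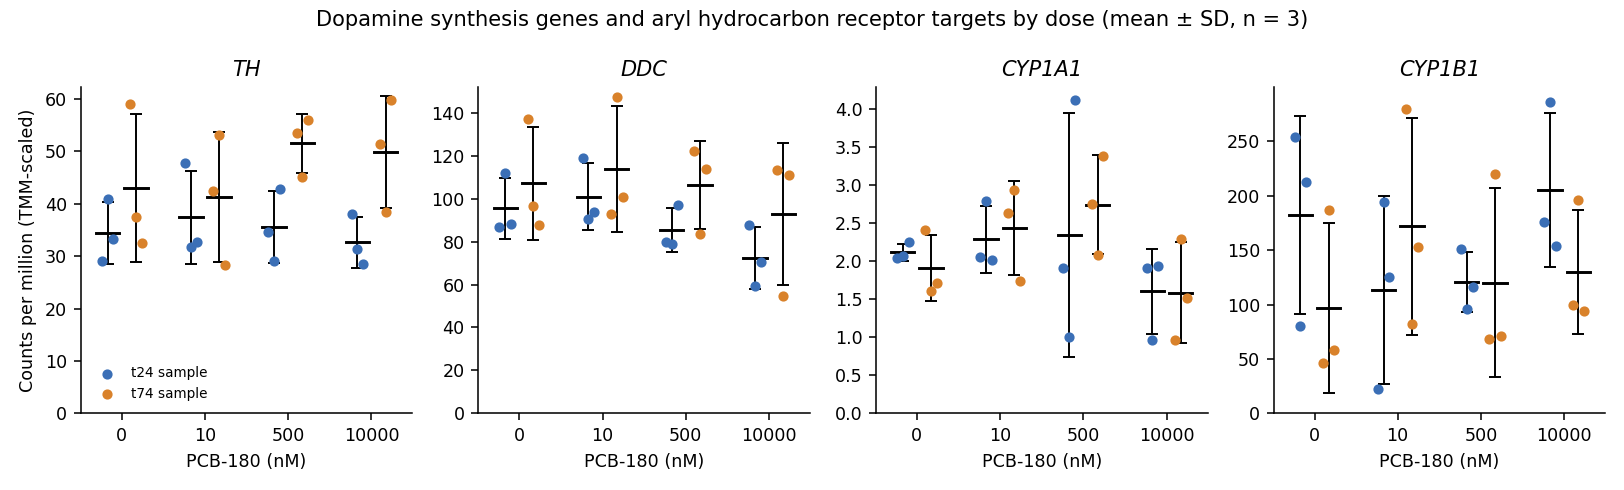
CPM (linear axes) of TH, DDC, CYP1A1 and CYP1B1 in each of the 24 samples by PCB-180 dose, with t24 and t74 in separate colours, and lines and bars for the mean and SD of 3 samples. TH at 10000 nM and t74 averaged 49.9 CPM against 43.0 CPM at 0 nM, and samples of each dose overlapped those of 0 nM in TH, DDC and CYP1B1.

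No single target of the aryl hydrocarbon receptor, which dioxin-like biphenyls activate, was called over all genes at any dose. CYP1A1, the classical target, averaged 2.13 ± 0.739 CPM (SD, n = 24). Its log2 difference was −0.40 ± 0.42 at 10000 nM and t24, and −0.27 ± 0.42 at 10000 nM and t74, where it had 1.59 ± 0.665 against 1.91 ± 0.438 CPM. CYP1B1 was far more abundant and less stable, at 143 CPM with a range from 22.3 to 286 CPM. The 3 samples at 10 nM and t24 had 22.3, 194 and 125 CPM, an 8.71-fold range within 1 group. PMEL, a melanosome gene chosen after its values were seen, ranged from 2.14 to 1059 CPM over the 24 libraries, with its lowest level in the library that was lowest in CYP1B1. As a list, the 12 receptor targets were higher at 10000 nM and t74 by camera (median +0.405, 10 of 12 above 0, adjusted p = 0.0271, and adjusted p = 0.516 with an estimated correlation). In that comparison 0 members passed over all genes and 1 was called adjusted over the list alone, and the list call ended without 10000 nM t74 replicate 2 (adjusted p = 0.639 by camera). Camera did not call the list of CAR and PXR xenobiotic targets at t24 (adjusted p = 0.815, 0.912 and 0.423 at 10, 500 and 10000 nM). The ryanodine receptor and calcium handling list was not called there either (adjusted p = 0.407, 0.327 and 0.138 by camera). At t74 neither list was called.

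No gene passed in any of the 12 dose comparisons. At t24, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes at 10, 500 and 10000 nM, while 187, 991 and 763 of 25592 genes had an unadjusted p under 0.05. At t74 it called 0 genes at each dose, with 688, 628 and 1791 genes under that level. Limma-voom also called 0 genes in all of these. DESeq2 called 1, 0 and 8 genes at t24 and 11, 8 and 4 at t74. The 1 gene at 10 nM and t24 had no symbol, and the 4 at 10000 nM and t74 were LY6K, MMP23A, INE2 and TMEM139-AS1, of which all but LY6K were chosen for naming after their values were seen. All 49 DESeq2 calls in the 12 dose comparisons had at least 1 group without a single count, and in 7 of them the gene, TMEM139-AS1, had not passed the main filter. The smallest share of genes at an unadjusted p under 0.05 was 0.731%, at 10 nM and t24, and the largest was 7.0%, at 10000 nM and t74.

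At 10 nM and t24, the serotonin receptor gene HTR2C had 21.3 ± 3.84 CPM (SD, n = 3) against 8.28 ± 2.19 CPM at 0 nM, a log2 difference of +1.37 ± 0.34. NDNF, a neurotrophic factor gene, was at +0.71 ± 0.18 and the carboxypeptidase-like gene CPXM2 at +0.93 ± 0.28. These 3 genes were among the smallest unadjusted p-values and did not pass. Camera called 6 lists, all with adjusted p = 0.948 with an estimated correlation. Ribosomal protein genes were lower in all 36 members (median −0.134), the 13 mitochondrially encoded genes were all higher (median +0.408), and 15 of 17 interferon response genes were higher (median +0.425). ISG15, an interferon-induced modifier, had 5.69 ± 4.41 against 2.34 ± 0.228 CPM, and the interferon call ended without 10 nM t24 replicate 1 (adjusted p = 0.816 by camera). Choroid plexus markers had a median of +0.687, with TTR at 787 ± 180 against 426 ± 12.5 CPM, while metallothioneins (median −0.336) and extracellular matrix genes (median −0.155) were lower. Each of these 6 calls ended without at least 1 library, and with the block for sample-sheet sets camera called 3 lists in this comparison. With the correction for gene length and GC content, the ribosomal median on log-CPM went from −0.121 to −0.0487 and stayed called (adjusted p = 0.0283 by camera), while that of metallothioneins went from −0.324 to −0.206 and was not called (adjusted p = 0.189 by camera).

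At 500 nM and t24, genes of GABAergic neurons stood higher as a group. The vesicular GABA transporter gene SLC32A1 had 6.91 ± 4.96 CPM (SD, n = 3) against 0.678 ± 0.33 CPM at 0 nM (+3.37 ± 1.12), and the forebrain interneuron transcription factors DLX5 and DLX6 were at +3.96 ± 1.34 and +2.92 ± 0.98. Of 13 measured members 0 passed over all genes, and 5 were called adjusted over the list alone. Camera called the list (median +1.46, and +0.987 on log-CPM, adjusted p = 0.00095, and adjusted p = 0.921 with an estimated correlation). The call held without each library in turn. In the 0 nM controls themselves the list's median on log-CPM was 1.81 lower at t24 than at t74. All 23 extracellular matrix genes (median −0.399) and all 14 mesenchymal markers (median −0.53) were lower, with COL6A2 at 32.4 ± 6.96 against 51.3 ± 10.7 CPM and FBN1, the fibrillin-1 gene, at 289 ± 76 against 422 ± 56 CPM. Camera called both lists, with adjusted p = 0.921 with an estimated correlation, and both calls ended without 500 nM t24 replicate 2. Smaller shifts called by camera were those of neuronal genes (median +0.127), cholesterol biosynthesis (+0.11) and the ATF4 and unfolded protein response (−0.173), each with adjusted p = 0.921 with an estimated correlation. Each of these 3 calls ended without at least 2 of the 6 libraries. That of the ATF4 and unfolded protein response also ended with the length and GC correction (adjusted p = 0.0624 by camera). Without 500 nM t24 replicate 3, the library with the fewest genes above 0, camera called 17 lists in place of 6. LEFTY2, an inhibitor of Nodal signaling, had 5.18 ± 1.84 against 11.4 ± 1.61 CPM (−1.14 ± 0.26) and did not pass, except with limma-voom with sample weights (adjusted p = 0.043).

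At 10000 nM and t24, all 23 cell cycle genes were higher than at 0 nM, with a median log2 difference of +0.711. CENPF, a kinetochore protein gene, had 44.6 ± 2.61 CPM (SD, n = 3) against 17.8 ± 6.35 CPM, the transcription factor gene E2F1 14.4 ± 1.83 against 8.52 ± 2.42 CPM, and MCM7, a subunit of the replicative helicase, 89.8 ± 22.1 against 54.5 ± 15.4 CPM. Cholesterol biosynthesis genes were higher in 21 of 23 members (median +0.246), with SQLE, the squalene epoxidase gene, at 325 ± 26.1 against 231 ± 12.3 CPM. Camera called both lists (adjusted p = 1.3e-13 and 9.1e-05), and both calls held without each library in turn, but both had adjusted p = 0.727 with an estimated correlation. Neural progenitor markers were higher in 14 of 16 members (median +0.913), with NOTCH1 at 36.0 ± 17.9 against 19.1 ± 4.6 CPM; that call had adjusted p = 0.727 with an estimated correlation and ended without 10000 nM t24 replicate 2 (adjusted p = 0.106 by camera). The other lists that camera called were replication-dependent histones (median +0.372), extracellular matrix (+0.206), axon guidance (+0.17), the ATF4 and unfolded protein response (−0.162) and the nuclear-encoded respiratory chain (−0.08). All had adjusted p = 0.727 with an estimated correlation, and none of their members passed. Each of these 5 calls ended without at least 2 of the 6 libraries. SPR, which encodes sepiapterin reductase of the pathway to the tyrosine hydroxylase cofactor, had 1.70 ± 0.487 against 4.33 ± 0.45 CPM (−1.34 ± 0.35) and GNB3, a G protein subunit gene, 26.0 ± 0.84 against 43.3 ± 2.34 CPM (−0.74 ± 0.20). Neither passed.

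At 10 nM and t74, all 8 choroid plexus markers were higher (median +0.683), with FOLR1, a folate receptor gene, at 3.95 ± 0.682 CPM (SD, n = 3) against 2.3 ± 0.569 CPM. GABAergic markers had a median of −1.30, with GAD1 at 21.0 ± 4.07 against 51.5 ± 42.5 CPM. The median of this list on log-CPM was 1.81 higher at t74 than at t24 in the 0 nM controls themselves, which all doses share. Cell cycle genes (median −0.278) and histones (median −0.268) were lower. Camera called these 4 lists, all with adjusted p = 0.991 with an estimated correlation, and each call ended without at least 2 of the 6 libraries. The calls of GABAergic markers and cell cycle genes also ended with the length and GC correction (adjusted p = 0.057 and 0.0601 by camera). At 500 nM and t74 the only list that camera called was the ATF4 and unfolded protein response, higher in 20 of 22 members (median +0.12). PHGDH, the first enzyme of serine synthesis, had 69.8 ± 7.52 against 56.1 ± 4.54 CPM. That call had adjusted p = 0.953 with an estimated correlation and ended without 0 nM t74 replicate 3 (adjusted p = 0.928 by camera). RENBP, the renin-binding protein gene, had 8.73 ± 3.17 against 4.05 ± 0.762 CPM (+1.11 ± 0.29) and did not pass.

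At 10000 nM and t74, neuronal genes lay lower and NRF2 targets higher, and 1 library carried most of both shifts. The 28 general neuronal and synaptic genes had a median of −0.343, with 27 below 0. Their median difference from the controls was −1.27 in replicate 2, against −0.0107 in replicate 1 and −0.116 in replicate 3. DCX, the gene of the microtubule protein doublecortin, had 1248 ± 672 CPM (SD, n = 3) against 1971 ± 289 CPM. All 19 targets of NRF2, the regulator of oxidative stress genes, were higher (median +0.384), with medians of +1.01 in replicate 2 and +0.0487 and +0.131 in replicates 1 and 3. NQO1, a quinone reductase gene, had 185 ± 190 against 58.0 ± 17.1 CPM (+1.68 ± 0.46), and FTL, the ferritin light chain gene, 2237 ± 1612 against 1082 ± 179 CPM. Of these 19 genes 0 passed over all genes and 4 were called adjusted over the list alone.

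Camera called 18 of the 42 lists at 10000 nM and t74, and none of the 18 was called with an estimated correlation (adjusted p between 0.516 and 0.773). Besides neuronal genes and NRF2 targets, the largest medians were those of metallothioneins (+1.08, 7 of 7 above 0, with +0.342, +1.41 and +0.968 in replicates 1, 2 and 3), GABAergic markers (−1.39), choroid plexus markers (+0.595), immediate early genes (−0.485) and NF-kB and cytokine genes (+0.435). Interferon response (+0.427), p53 targets (+0.267), lysosome and autophagy (+0.179), ribosomal proteins (+0.169) and the ATF4 and unfolded protein response (+0.115, lowest in replicate 2 at +0.0727) were higher. Glutamatergic markers (−0.335), cell cycle genes (−0.329), ion channels (−0.309), synaptic plasticity (−0.255) and cholesterol biosynthesis (−0.164) were lower. Examples are the immediate early gene EGR1, with 19.8 ± 4.6 against 33.8 ± 10.1 CPM (SD, n = 3), and the p53 target CDKN1A, with 327 ± 145 against 194 ± 71.7 CPM. With the length and GC correction, ribosomal proteins went from a median on log-CPM of +0.147 to +0.0375 and were no longer called (adjusted p = 0.524 by camera). Choroid plexus markers and NF-kB and cytokine genes went from +0.523 to +0.567 and from +0.455 to +0.441 and also missed the threshold (adjusted p = 0.0615 each by camera). Medians moved by more than 1.5-fold for cholesterol biosynthesis (−0.239 to −0.157) and ion channels (−0.363 to −0.238), which stayed called. Without replicate 2 of this group, 4 of the 18 lists were still called, and without 0 nM t74 replicate 3, 7 were.

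**Figure D2:**
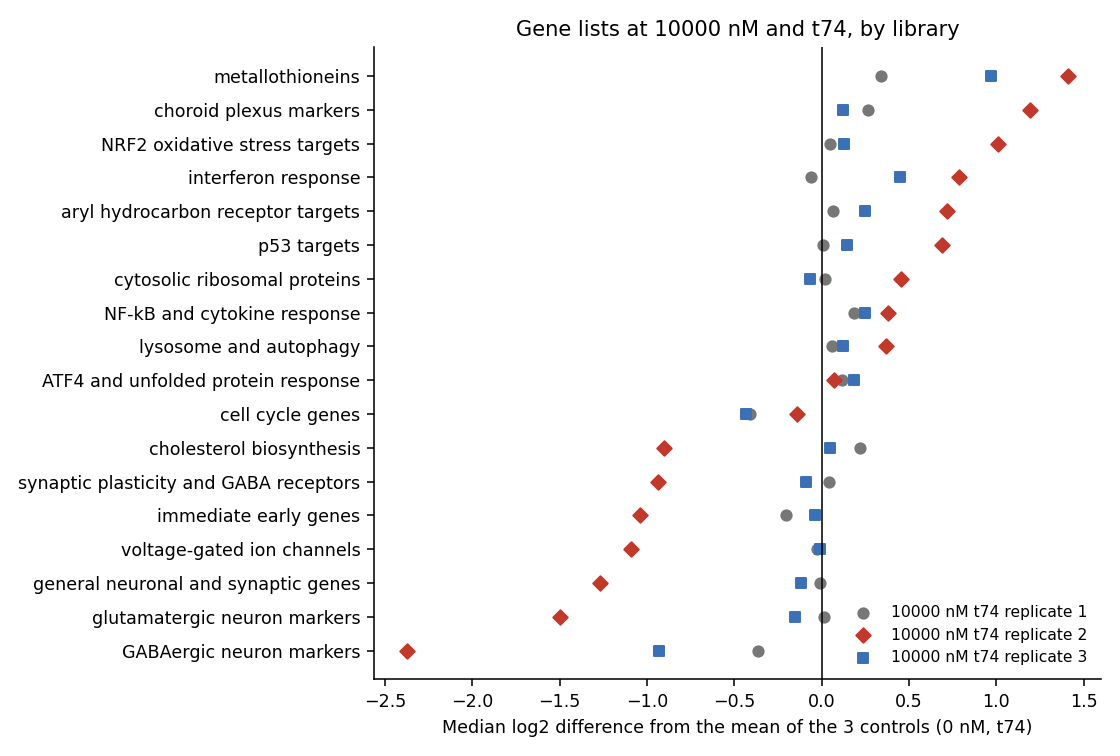
Median log2 difference of each of the 18 lists called at 10000 nM and t74 from the mean of the 3 controls (linear axis), with 1 marker per treated library. Neuronal genes stood at −1.27 in replicate 2 and at −0.0107 and −0.116 in replicates 1 and 3.

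Among the smallest unadjusted p-values at 10000 nM averaged over both times was that of KLHL1, a Kelch-family gene of neurons. KLHL1 had 7.5 ± 1.37 CPM (SD, n = 6) against 11.4 ± 0.905 CPM at 0 nM (−0.61 ± 0.13), with no overlap between the groups at either time. Chance alone separates 10% of genes in a comparison of 3 against 3 samples at a single time. The lower share for both times together was not worked out. SREBF1, a regulator of lipid synthesis, had 44.7 ± 6.05 against 32.6 ± 4.76 CPM (+0.45 ± 0.11). Neither passed (adjusted p = 0.987 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Averaged over both times, edgeR, limma-voom and their alternatives gave 0 calls at every dose, while DESeq2 called 4, 4 and 1 genes at 10, 500 and 10000 nM, and 503, 691 and 1018 genes had an unadjusted p under 0.05. Those with a symbol, named after their values were seen, were POM121L12 and TMEM139-AS1 at 10 and 500 nM and TMEM139-AS1 at 10000 nM. Camera called 6, 0 and 13 lists, none with an estimated correlation (adjusted p from 0.625 to 0.978 among called lists). With the length and GC correction the counts were 4, 0 and 14. Without that correction and with 1 library left out they ran from 1 to 7, 0 to 7 and 4 to 19. At single times the counts of lists also moved, from 1 to 15, 2 to 17 and 4 to 12 at t24 and from 0 to 8, 0 to 11 and 5 to 20 at t74 (10, 500 and 10000 nM). At 10000 nM, immediate early genes (median −0.307, 15 of 16 below 0) and ion channels (−0.226, 21 of 22 below 0) held without each library in turn, each with adjusted p = 0.625 with an estimated correlation. At 10 nM, choroid plexus markers (+0.617) held likewise, with adjusted p = 0.978 with an estimated correlation.

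Dose effects that differed between t74 and t24 were not found for any gene. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes at each dose and limma-voom 0, DESeq2 called 4, 3 and 1 at 10, 500 and 10000 nM, and 449, 1172 and 1635 genes had an unadjusted p under 0.05. The DESeq2 calls with a symbol, likewise named after their values were seen, were POM121L12 and PMS2P8 at 10 nM, CLIC3 and POM121L12 at 500 nM and TMEM139-AS1 at 10000 nM. The lipid transfer gene STARD10 (+1.22 ± 0.27) and the condensin gene SMC2 (−0.90 ± 0.21) were among the smallest p-values at 10000 nM and did not pass. The doses were also compared with each other over 16420 genes with a mean CPM of at least 1. Log2 differences from the shared controls correlated across genes, which are not independent replicates, at 0.345, 0.159 and 0.382 at t24 (10 with 500, 10 with 10000 and 500 with 10000 nM). Simulated unchanged groups against those controls gave 0.50, 0.501 and 0.50. At t74 the correlations were 0.451, 0.557 and 0.481, against 0.499, 0.494 and 0.499 when simulated. Covariances at t24 were 0.0378, 0.0162 and 0.0563, against simulated values of 0.0673, 0.0672 and 0.067. Covariances at t74 were 0.0455, 0.0716 and 0.0599, against simulated values of 0.0666, 0.0659 and 0.0664. The 3 control libraries per time cannot be parted into sets of at least 2 libraries each, so the controls were not split, and the correlations hold a part from the shared controls.

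The comparison of times had 12 samples on each side, more than any dose comparison. Between t24 and t74, averaged over the doses, 20 genes rose and 73 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 against 12 samples), with a median change of 1.28-fold. Among called genes that reached 1 CPM at either time none changed by more than 2.17-fold. Below that level the largest fitted change was 47.1-fold, an imprecise value, since that gene averaged 0.0121 CPM at t24 and 0.36 CPM at t74. OGDH, which encodes a subunit of the 2-oxoglutarate dehydrogenase of the citric acid cycle, fell from 168 ± 7.4 CPM (SD, n = 12) to 118 ± 10.7 CPM (−0.52 ± 0.04, adjusted p = 3.4e-06, chromosome 7 at 44606572 to 44709066). YEATS2, a histone reader gene, fell from 69.6 ± 7.47 to 49.0 ± 4.16 CPM (−0.50 ± 0.06) and PAN2, of the poly(A) nuclease complex, from 23.0 ± 2.91 to 15.4 ± 2.29 CPM. OBSL1, ZNF607, IFT140, ZMYM3, ZSWIM8 and SSBP4 fell by 0.27 to 0.47 log2 units, and ATMIN, a DNA damage response gene, rose from 133 ± 6.05 to 153 ± 6.78 CPM (+0.20 ± 0.04), a call that was kept in 18 of 33 alternatives. These 10 genes were those with no overlap between all 12 samples of each time. Of the 92 called genes listed one by one, 90 had the same direction at all 4 doses. The genes were called on the mean over these doses, so such agreement was largely built in.

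**Figure D3:**
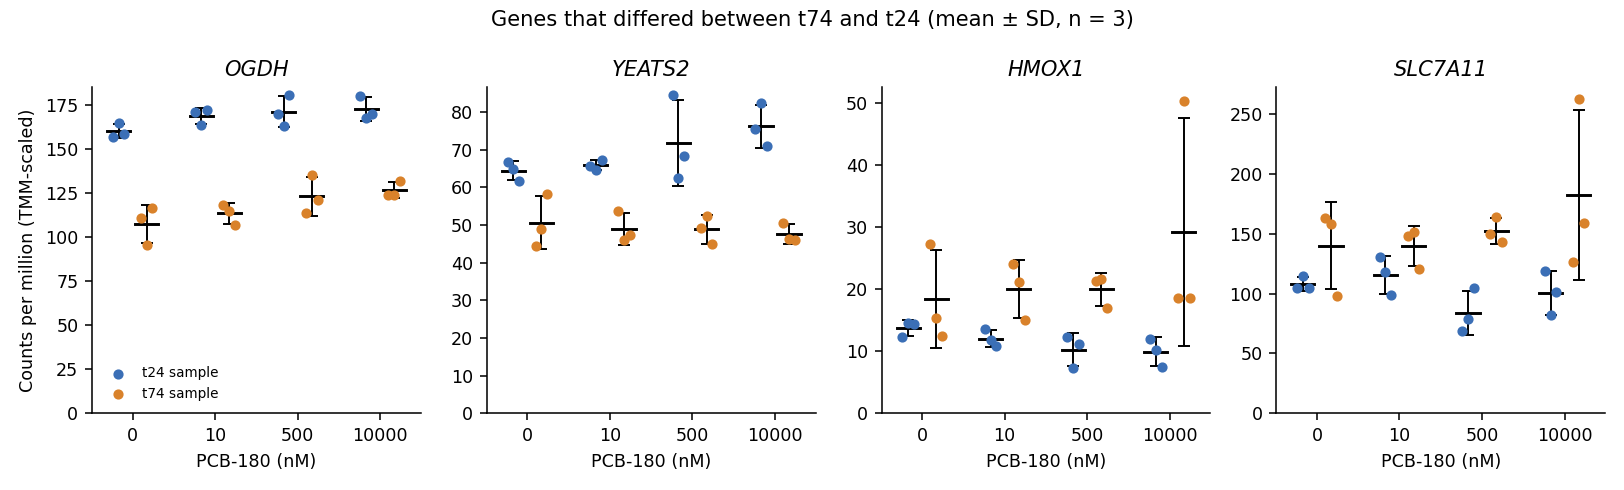
CPM (linear axes) of OGDH, YEATS2, HMOX1 and SLC7A11 in each of the 24 samples by PCB-180 dose, with t24 and t74 in separate colours, and lines and bars for the mean and SD of 3 samples. OGDH averaged 168 CPM at t24 and 118 CPM at t74 with no overlap, while HMOX1 averaged 11.5 and 21.9 CPM.

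The redox genes HMOX1 and SLC7A11 rose with time. HMOX1, the heme oxygenase gene, rose from 11.5 ± 2.34 CPM (SD, n = 12) to 21.9 ± 9.87 CPM (+0.92 ± 0.17, adjusted p = 0.0189 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SLC7A11, the cystine importer gene, rose from 102 ± 18.2 to 154 ± 39.5 CPM (+0.59 ± 0.11, adjusted p = 0.0233 by the same test). The call of SLC7A11 ended without each of 6 libraries in turn (highest adjusted p = 0.0592 by the same edgeR test, without 10 nM t24 replicate 3). The rises on log-CPM at 0, 10, 500 and 10000 nM were 0.343, 0.714, 0.986 and 1.41 for HMOX1 and 0.333, 0.277, 0.879 and 0.81 for SLC7A11, so the averages rest more on the higher doses. Without 10000 nM t74 replicate 2 both still passed (+0.754 and +0.498). Both belong to the NRF2 targets, of which 2 of 19 rose, 0 fell and 17 did not pass; 9 were called adjusted over the list alone, and 15 lay above 0 (median +0.212). At 0 nM the list's median on log-CPM was +0.0166, against +0.472 at 10000 nM. The ATF4 and unfolded protein response had a median of +0.129 with 16 of 22 above 0, and 7 members called adjusted over the list alone. Its medians on log-CPM at 0, 10, 500 and 10000 nM were −0.0472, −0.0254, +0.25 and +0.171, so it was not higher at 0 or 10 nM.

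Averaged over the doses, respiratory chain and glycolysis genes were slightly higher and cell cycle genes lower at t74. Of 35 nuclear-encoded respiratory chain genes, 31 lay above 0 (median +0.155) and 16 were called adjusted over the list alone. With the length and GC correction their median on log-CPM went from +0.148 to +0.0807 and the list stayed called (adjusted p = 5.9e-10 and then 0.0012 by camera, and adjusted p = 0.832 with an estimated correlation). ATP5MC1, an ATP synthase subunit gene, had 28 ± 3.33 against 23.5 ± 1.38 CPM (SD, n = 12). Glycolysis and hypoxia genes were higher in 21 of 24 members (median +0.103), with 5 called adjusted over the list alone and LDHA, the lactate dehydrogenase gene, at 279 ± 49.3 against 213 ± 31.4 CPM. All 23 cell cycle genes were lower (median −0.557), 9 of them called adjusted over the list alone, mostly from the highest dose (medians on log-CPM of −0.0556, −0.219, −0.273 and −1.15 at 0, 10, 500 and 10000 nM), with TOP2A at 18.4 ± 7.46 against 36.3 ± 19.1 CPM and CDK1 at 8.13 ± 2.21 against 13.7 ± 5.29 CPM. All 13 histone genes were lower (median −0.265), 4 of them called adjusted over the list alone, with medians on log-CPM of +0.0421 at 0 nM and −0.57 at 10000 nM. Ribosomal proteins (+0.107) and proteasome subunits (+0.067) had higher medians, and extracellular matrix (−0.218) and axon guidance genes (−0.144) lower ones, each with 0 members called adjusted over the list alone. No member of these 8 lists passed over all genes, although 9 of the members picked by the naming rule did with DESeq2: ENO1, LDHA, ATP5MC1, UQCRB, CCNB1, CDK1, TOP2A, H2BC21 and COL2A1 (adjusted p between 0.00118 and 0.0254). Camera called these 8 lists and the 2 stress lists, none with an estimated correlation: adjusted p = 0.359 with an estimated correlation for glycolysis and hypoxia, 0.947 for ribosomal proteins and 0.832 for the other 8. Fry's directional test called glycolysis and hypoxia alone (adjusted p = 0.0196), and its mixed test, which ignores direction, called 6 lists (lowest adjusted p = 0.0138).

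TH had 46.4 ± 10.6 CPM (SD, n = 12) at t74 against 35.0 ± 6.1 CPM at t24 (+0.40 ± 0.12). It did not pass in the main test (adjusted p = 0.136 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but did with DESeq2 (adjusted p = 0.0315) and with limma-voom with sample weights (adjusted p = 0.0176). The count of 93 genes was 96 with limma-voom on the same genes (21 rose and 75 fell, 88 of them shared) and depended on other choices and on single libraries. There were 797 calls by DESeq2 with its own size factors and filter over 41918 genes (344 rose and 453 fell), 1423 by limma-voom with sample weights (547 rose and 876 fell), 260 under the stricter filter (143 rose and 117 fell), and 36 to 272 with 1 library left out. After the correction for gene length and GC content, 54 genes passed (28 rose and 26 fell), 39 of them among the 93; IFT140, ZMYM3 and ZSWIM8 no longer passed. Among the lists, the calls of ribosomal proteins, proteasome subunits and axon guidance ended, with medians on log-CPM from +0.105 to +0.00701, +0.0665 to +0.0143 and −0.185 to −0.12. The unadjusted p was under 0.05 for 3452 genes.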

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

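Among the tests below, the choice of replicate 2 at 10000 nM and t74 from the planned omission of each library, the test for fewer neurons in that library and all tests with the length and GC correction were chosen only after the result was seen. The 26 flagged results are gene lists whose dose effect differed between t74 and t24, by the dose by time contrast with camera at its preset correlation. None was called with an estimated correlation (adjusted p between 0.674 and 0.893). Values are median log2 differences, t74 minus t24. At 10 nM, extracellular matrix genes stood at 0.465 and GABAergic markers at −1.502. At 500 nM, the lists with a higher effect at t74 were the ATF4 and unfolded protein response (0.302), extracellular matrix (0.529), lysosome and autophagy (0.201), mesenchymal markers (0.583) and p53 targets (0.314). Those with a lower effect were cell cycle genes (−0.363), cholesterol biosynthesis (−0.167), GABAergic markers (−2.186), neuronal genes (−0.171) and histones (−0.446). At 10000 nM, the higher ones were the ATF4 and unfolded protein response (0.295), interferon response (0.966), lysosome and autophagy (0.193), NRF2 targets (0.508), the respiratory chain (0.125) and p53 targets (0.299). The lower ones were axon guidance (−0.314), cell cycle genes (−1.108), cholesterol biosynthesis (−0.394), GABAergic markers (−1.855), neuronal genes (−0.234), glutamatergic markers (−0.403), histones (−0.554) and synaptic plasticity (−0.196). Only the cell cycle call at 10000 nM and the GABAergic calls at 500 and 10000 nM held without each library in turn. For GABAergic markers much of the difference lay in the shared controls, whose median on log-CPM was 1.81 higher at t74 than at t24, against −0.806 at 500 nM and −0.412 at 10000 nM. Extracellular matrix genes were at −0.495 at 0 nM, against −0.0274 and 0.111 at 10 and 500 nM. With the length and GC correction, the calls of cell cycle genes, p53 targets and lysosome and autophagy at 500 nM and of synaptic plasticity at 10000 nM ended (adjusted p = 0.0606, 0.0776, 0.0776 and 0.125 by camera). Single values in groups of 3 samples were not tested for standing apart, and every sample entered the main comparisons. The lowest sample weights in limma-voom were 0.198 for 10000 nM t74 replicate 2 and 0.27 for 500 nM t24 replicate 3.

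The first pattern is the shift at 10000 nM and t74, where neuronal lists were lower and stress lists higher. Without replicate 2 of that group 4 of the 18 called lists stayed past the threshold, against 15 and 15 without replicates 1 and 3, which is consistent with replicate 2 carrying most of the shift on the treated side. Not every list followed it, since the ATF4 and unfolded protein response and the cell cycle genes deviated least in replicate 2 (medians of +0.0727 and −0.143) and metallothioneins were also high in replicate 3 (+0.968). Of the controls, 7 of the lists stayed without 0 nM t74 replicate 3, against 17 and 16 without replicates 1 and 2, so the calls also rested on that library. A trend in gene length and GC content as the whole cause is argued against by the 15 of the 18 lists that stayed past the threshold after the correction. Of the lists whose calls ended, ribosomal proteins lost most of their median (+0.147 to +0.0375), so for them the trend could be the cause. Fewer neurons and more of every other cell type in that library cannot be told from the data. Its 7 non-neuronal lists all had a median above the other 5 libraries, but the lowest was 0.00616 for mesenchymal markers and 0 of the 7 exceeded 2 standard errors. These standard errors came from the spread between the genes of a list with a mean CPM of at least 1, not between libraries.

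The second pattern is the change with time, in which 73 genes fell and 20 rose. A length and GC trend as the whole cause is argued against by the 54 genes that passed over all genes after the correction (28 rose and 26 fell). The folds of the 93 genes cannot settle this, since their rule was added later and the genes were chosen for large folds. The median log2 of the genes that fell went from −0.351 to −0.282 (median SE 0.0662 and 0.0621), and that of the genes that rose from +0.417 to +0.447 (median SE 0.079 and 0.0794). The correction took away the excess of falls: calls ended for 49 of the 73 genes that fell and 5 of the 20 that rose. The count of falls therefore depended on the trend. Whether that trend is technical or part of the change with time cannot be told from the correction. Of the 93 genes 39 stayed past the threshold, fewer than the majority predicted without such a trend. By the rule first written for this test, that count went with the trend. The 49 genes that fell and lost their calls went from a median of −0.322 to −0.24 (median SE 0.0631 and 0.0614), and their median adjusted p from 0.0315 to 0.0945. Those calls ended because the folds shrank while the SE hardly moved. At the median most of the fold was left, but 3 of the 49 genes lost at least 50% of theirs. The genes that fell had a median GC content of 56.4% and those that rose 43.2%, against 49.8% for the tested genes. Their median effective lengths were 3335 and 2504, against 1738 for the tested genes. Over 11663 genes with a mean log-CPM above 3, the log2 change with time followed length more than GC content (Spearman rho = −0.308 and −0.141). After the correction these were 0.0111 and 0.00686. Of the 20 genes that rose, 15 stayed past the threshold after the correction. Sequencing depth is unlikely as an explanation, since 85 of the 93 stayed past the threshold with every library thinned to the lowest total.

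Regrouping the samples asked how often other groupings give as many genes at an unadjusted p under 0.05. For 3 against 3 samples the 10 splits are too few for a share under 0.05. At t24, 7 splits gave as many as the real 187 at 10 nM (highest other 1806), 4 as many as 991 at 500 nM (highest other 2645) and 2 as many as 763 at 10000 nM (highest other 1006). At t74 the numbers were 10 for 688 at 10 nM (highest other 1813), 9 for 628 at 500 nM (highest other 1897) and 5 for 1791 at 10000 nM (highest other 2686). Averaged over both times, 36, 30 and 21 of 40 splits gave as many as the real 503, 691 and 1018 (highest other 2197, 3349 and 2943), so chance could not be excluded. For the difference between the times, 34, 13 and 7 of 40 splits gave as many as the real 449, 1172 and 1635 (highest other 2838, 3138 and 2620), so chance could not be excluded there either. Of the other splits for the 10 nM difference, 4 had calls, with 405 in 1 of them, and the cause was not tested. For t74 against t24, only the real grouping, 1 of 100, reached 93 calls and the highest other had 1. Chance could be excluded only if the libraries were independent, which the labels do not say. In each set the t24 samples also had lower sample-sheet numbers than the t74 samples. The splits therefore cannot part time from anything that followed that order.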

How the results depend on the processing

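Limma-voom with sample weights, omission of the 2 libraries with the fewest genes, the length and GC correction and the shuffles of the sets were chosen only after the results had been seen. The 12 dose counts of 0 stayed at 0 under limma-voom, RLE size factors, both other filters, the compared groups alone, the block and the correction. DESeq2 gave 1 gene at 10 nM and t24, 8 at 10000 nM and t24, 11 at 10 nM and t74, 8 at 500 nM and t74, 4 at 10000 nM and t74, 4, 4 and 1 at 10, 500 and 10000 nM averaged over both times, and 4, 3 and 1 for the difference of the 10, 500 and 10000 nM effects between t74 and t24; all 49 had a group without a count. At 500 nM and t24, limma-voom with sample weights gave 3 genes, and leaving out 1 library gave 0 to 3. The 93 genes that changed with time became 797 with DESeq2 and its own filter (41918 genes), 260 under the stricter filter, 1423 with sample weights, 54 after the correction and 176 without the 2 libraries with the fewest genes. Leaving out 1 library gave 36 to 272, the lowest without 10 nM t24 replicate 3 and the highest without 500 nM t24 replicate 3. The stricter filter tested fewer genes (16333); for the others the cause was not tested. The sample-sheet sets were not treated as pairs, since only 1 of 18 pairs had a residual correlation over 0.1. Residuals of the same set had a median correlation of 0.02 against −0.00949. As a hint from the data that sets share something, 17 of 24 samples correlated best with their own set, against a mean of 8.03 when the sets were shuffled at random within groups (p = 0.0046). As a block they gave 106 genes for time and 0 for every dose comparison. Lists called under the block were 3 in place of 6 at 10 nM and t24, 3 in place of 4 at 10 nM and t74, 2 in place of 1 at 500 nM and t74, 17 in place of 18 at 10000 nM and t74, 3 in place of 2 for the 10 nM difference between the times and 11 in place of 10 for time. At 10000 nM and t24 the count stayed at 8, with GABAergic markers in place of extracellular matrix, and no other list call changed. OGDH, YEATS2, OBSL1, PAN2, ZNF607, SSBP4 and HMOX1 passed under all 33 alternatives, with OGDH between −0.54 and −0.42. ATMIN passed in 18, SLC7A11 in 27. No named gene changed sign where it was called in the main test or in the alternative. Only 12 of the 100 gene results were called in the main test, and sign changes without a call were not counted. Of 2088 alternative values for the 100 gene results, 2016 kept their side of the threshold, 24 fell short of it and 48 newly passed. Of these 48, 47 were for time and 1 was LEFTY2. In a simulated comparison of 3 against 3 samples 66% of 2-fold and 20% of 1.5-fold changes in the more abundant genes were called. Dose effects of 1.5-fold or less were therefore mostly out of reach at this spread and depth.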

Other observations

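Of the tests in this part, those with PAX6 and with the pigment cell markers were chosen only after the result was seen. Pigment cell genes differed in how much they varied between replicates of the same group. In groups without a 0, the highest fold within 1 group was 665 for TYRP1, 597 for DCT, 328 for PMEL and 84.5 for TYR, between 4.33 and 11.6 for 8 others and 1.72 for BEST1. DCT, a melanin synthesis enzyme, ranged from 0.967 to 875 CPM over the 24 libraries, TYRP1, of the same pathway, from 0.532 to 913 CPM, TYR, the tyrosinase gene, from 0.499 to 72.4 CPM and MITF, their transcription factor, from 4.87 to 48.2 CPM. At 10 nM and t24 the 3 replicates had 2.14, 703 and 243 CPM of PMEL, and at 0 nM and t74 53.3, 693 and 190 CPM. These genes were chosen after the range of PMEL and its correlation with CYP1B1 had been seen.

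The third pattern is the spread of CYP1B1 between replicates, described with residuals from the group means over all 24 libraries. The mean of 12 pigment cell markers, PMEL left out, had a Pearson r of 0.883 with CYP1B1 (Spearman rho = 0.823, and r = 0.813 without the 2 libraries farthest from their median). PAX6 had r = 0.543 (rho = 0.485, and r = 0.458 without 2 libraries), with r = 0.818, 0.662 and −0.121 within the 3 sample-sheet sets. No p-value is given for these relations, since the markers were chosen after PMEL had been seen to follow CYP1B1, and DCT (r = 0.892) is itself among the genes closest to CYP1B1. The genes closest to CYP1B1 were mostly not pigment genes, with PKDCC at r = 0.954, TGIF2 at 0.933, KIRREL1 at 0.929, FZD2 at 0.92, TEAD2 at 0.91 and YAP1 at 0.902, against 0.908 for PMEL and 0.323 for RPE65. These genes were named after their values were seen. A differing pigment cell share and another shared source cannot be told apart, because many genes that do not mark pigment cells follow CYP1B1 as closely. With 8 other aryl hydrocarbon receptor targets, a test planned before its result, the relation was open (r = 0.358, permutation p = 0.086 over 100000 two-sided permutations; rho = 0.37, permutation p = 0.075; r = 0.309 without 2 libraries), with r = 0.211, 0.574 and −0.00172 within the sets.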
